A study of Homo sapiens with 14 samples.

How the data were processed

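Peak lists of 4 ChIP-seq samples of HL60 cells were used: SKI in unmodified cells (2 lists), SKI in CRISPR/Cas9 control cells (1 list) and RUNX1 in unmodified cells (1 list). Groups and replicate numbers came from the sample titles. The other samples of the series were not analysed here. Per the labels' protocols, cells were grown in RPMI medium with serum, chromatin was crosslinked with formaldehyde and sonicated, and libraries were made with a low-input ChIP kit. Per the submitters' processing notes, bcl2fastq, Bowtie2, MACS 1.4 and deepTools were used, with the builds hg19 and GRCh37. The role of each tool is not given there, and the peak columns name MACS in the file headers. Which control library was set against each ChIP, and the sequencing depth, are not given in the sources used here. Peaks were listed per sample.

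Per the file headers, each deposited list gives the −log10 p-value of a peak, its fold enrichment as a ratio over background and its count of tags. The −log10 p-values started at about 5.00 in every list. Peaks with under 35 tags made up 1.70%, 5.47%, 5.19% and 3.46% of the lists. The deposited FDR column was not used, since its scale is not stated. The authors' position class, nearest Ensembl gene and signed distance to a TSS were read as deposited. For 18 peaks no transcript was listed.

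SKI peaks of the 3 lists that overlapped by at least 1 bp were joined into sites, and a site was called shared when it held a peak of every SKI list. Expected overlaps came from 10000 circular shifts of a list along its chromosomes, with one-sided permutation p-values. Fold enrichment of SKI peaks with and without RUNX1 was compared by the difference of medians, with 100000 permutations over the peaks of a list. Shares carry 95% Wilson intervals, which cover counting error only. TSS positions were rebuilt from the deposited distances as the median over the peaks of a transcript, which gave 39039 TSSs. The rebuilt and the deposited distances differed by a median of 6 bp, and by 300 bp at the 99th percentile. A TSS that was nearest to no peak is missing from this set. Promoter sites were those centred within 1000 bp of a rebuilt TSS, and genes counted as bound when a site lay within 10 kb of one.

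Gene lists were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 11 lists. The background was the 20056 protein-coding symbols of a RefSeq table for another build, used for names alone. Of the 13810 protein-coding genes named in the lists, 96.4% matched a current symbol, directly or by a synonym, and all 316 members of the 11 lists matched. Gene lists, tests, the rule for named sites and all alternatives but 1 were fixed before the data were examined. Under that rule the text names SKI, RUNX1 and CEBPB, the 15 shared sites with RUNX1 and the 10 without it that have the smallest worst rank of fold enrichment, the 10 strongest RUNX1 peaks outside every SKI peak, and up to 4 bound members per gene list. Sites wider than 5000 bp or on Y were not named among the ranked ones. Some members that the rule selects are not reported here. Further members given beside them were chosen after their values were seen.

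The tests were tried on simulated data. With the RUNX1 list placed at random the median fold over expectation was 0.936 and 0% of 20 draws passed 0.05. With 20% of RUNX1 peaks planted on SKI sites the excess recovered was 19.7%. For the permutation of medians in the control list, random groups passed 0.05 in 5% of draws, and an added difference of 2 came back as 2.05. Fisher's exact test passed 0.05 in 5.1% of 1000 random lists. Alternatives were a stricter threshold (−log10 p of at least 10), lists of equal length, leaving out each SKI list, other overlap rules, other expectations, width strata and other distances to a TSS. Lists of equal length held the 5581 peaks of highest −log10 p, with ties ranked by fold enrichment. The planned test of the RUNX motif needs the genome sequence of this build and was not run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.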

Results

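Chromatin immunoprecipitation followed by sequencing was used to map where the transcriptional corepressor SKI and the transcription factor RUNX1 bind in HL60, a human acute myeloid leukaemia cell line that can be driven to mature along the myeloid lineage. SKI acts through partner proteins, SMADs among them, whereas RUNX1 binds DNA directly and is required for blood cell formation. Of the 14 samples in the series, 4 peak lists were analysed. They comprised 2 SKI lists from unmodified cells, 1 SKI list from CRISPR/Cas9 control cells and 1 RUNX1 list from unmodified cells. The other 10 samples, among them cells with SKI deleted, the histone marks, IgG and CEBPB, were not analysed here. The SKI lists held 54841 peaks (unmodified cells, replicate 1), 14431 peaks (unmodified cells, replicate 2) and 14019 peaks (control cells), and the RUNX1 list held 5581. Median tags per peak were 97, 56, 61 and 56 in that order, and median peak widths were 710, 472, 691 and 553 bp. Total library depth was not given in the sources used here. Positions are on hg19 as listed in the deposited files. Fold enrichment is the authors' own value for a peak and is used to rank peaks within a list, except where lists were cut to equal length by −log10 p. As each kind of RUNX1 and control-cell list is a single sample, p-values describe these lists and not the spread between cultures.

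The first question was which SKI sites recurred across the 3 SKI lists. The SKI samples of cells with SKI deleted were not used here, so signal that does not depend on SKI could not be removed. SKI peaks recurred in all 3 lists at 8980 sites, out of 55146 regions with a peak in at least 1 of them. The SKIL promoter, the gene of the closest relative of SKI and a well-known TGF-beta target, held one of the strongest of these sites (chromosome 3, 170073465 to 170076733, centre at -367 bp from the TSS), with fold enrichments of 189, 218 and 239 in the 3 lists. The value of 218 was the highest in the list of unmodified cells, replicate 2. The gene SKI itself had 3 shared sites within 10 kb of a TSS, 2 of which carried a RUNX1 peak, with RUNX1 fold enrichments of 7.28 and 11.54. The stronger RUNX1 peaks at SKI, of 50.6 (at -1199 bp from a TSS) and 17.94, lay in no shared SKI site. RUNX1 had 4 shared SKI sites, 3 of them with a RUNX1 peak, including its promoter region (chromosome 21, 36418967 to 36423044; SKI fold enrichments of 112, 35.2 and 45.5; RUNX1 fold enrichment of 42.4). At CEBPB, which encodes a myeloid transcription factor, 1 shared SKI site (chromosome 20, 48806526 to 48810168) had no RUNX1 peak. Of the peaks in unmodified cells, replicate 2, 72.3% (95% Wilson interval 71.5 to 73.0) overlapped a peak of the control cells, against 0.774% expected from shifted positions. In the reverse direction the share was 69.3% (68.5 to 70.1), against 0.772%. The long list contained 97.4% of the peaks of replicate 2 and 97.5% of those of the control cells, with 3.20% and 3.60% expected. All of these overlaps had a one-sided permutation p of 0.0001, the smallest that 10000 shifts can give. Ranks of fold enrichment over the shared sites correlated with Spearman rho of 0.737 between the unmodified lists, 0.691 between replicate 1 and control cells, and 0.651 between replicate 2 and control cells, across sites, which are not independent replicates. With each list held to its 5581 peaks of highest −log10 p the number of shared sites was 3121. The list of replicate 1 carries row numbers up to 75197 of a longer table, of which 72.9% are present, and the filter is not stated.

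The second question was how far SKI and RUNX1 occupied the same sites. A RUNX1 peak overlapped 3004 of the 8980 shared SKI sites (33.5%, 95% Wilson interval 32.5 to 34.4), where 0.492% was expected, and 56.2% of RUNX1 peaks lay in a shared SKI site, where 0.810% was expected. The one-sided permutation p was 0.0001 for both. Shifted positions ignore where chromatin is open, so this test cannot separate joint binding from a shared preference for open regions. By list, 92.9% of RUNX1 peaks overlapped a SKI peak of unmodified cells, replicate 1, 60.4% one of replicate 2 and 70.7% one of control cells. The expected shares were 3.05%, 0.618% and 0.732%, so the fold over expectation was lowest for the long list (30.5, 97.8 and 96.7). Sites present in a single SKI list carried a RUNX1 peak in 2.86% of cases, those in 2 lists in 14.4% and those in all 3 in 33.5%. The single-list share was set by the long list, as 38710 of those 38863 sites were of replicate 1. Sites in 2 lists were mixed, at 6.12% for both unmodified lists and 20.2% for replicate 1 with control cells. For replicate 2 with control cells the share was 41.9% of 241 sites, above that of sites in all 3 lists. Where SKI and RUNX1 peaks overlapped, the distance between their summits had a median of 28, 35 and 36 bp in the 3 SKI lists. Summits placed at random within the SKI peak gave medians of 280, 127 and 194 bp. The fold over expectation was 68.0 for shifts along the chromosome and 35.7 for moves of 50 to 500 kb. It was 3.44 for sites within 1000 bp of a TSS, where RUNX1 promoter peaks were placed at other promoters (16.7% observed, 4.84% expected), and 137 for sites farther away (46.3% observed, 0.338% expected). Distal peaks were not placed at promoters, so the expectations of these classes are unlike and their folds should not be compared.

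By the rule fixed before the data were examined, 15 shared sites with RUNX1 and the best ranks in all 4 lists were named. The highest ranked lay at the promoter of CRK, which encodes a signalling adaptor (chromosome 17, 1366118 to 1367071, centre at -143 bp from the TSS), with SKI fold enrichments of 173, 98.1 and 87.2 and a RUNX1 fold enrichment of 85.2. Promoter sites also lay at PTK2, the gene of focal adhesion kinase, and AC018816.3. Upstream sites lay at CHST12 and APOD, and intronic ones in LDLRAD3, TYK2, a Janus kinase gene, and the EGR3 neighbourhood. Exonic sites were assigned to FARP2 and RP11-7F17.7, and intergenic ones to CTB-107P3.1, TSR2, RPL31P12, RP11-128L5.1 and RP11-96C21.1. Over these 15 sites the RUNX1 fold enrichment ranged from 49.9 to 217. The 10 best-ranked shared sites without RUNX1 had their nearest TSS at MARCH3, RP11-791M20.1, LYZL1, SLC7A5, AC098592.7, PIK3R5, RP11-640M9.1, MIR4439, RPL3P6 and UBL4A. The best ranked of these was in an intron (chromosome 5, 126306834 to 126309462) nearest MARCH3, with SKI fold enrichments of 168, 77.8 and 101. The site at SLC7A5, an amino acid transporter gene, had values of 141, 70.9 and 71.2. The 10 strongest RUNX1 peaks outside every SKI peak were nearest RP11-391M7.3, ST7, AC016696.1, ADARB2, ELOVL6, AL139812.1, ITIH5, RFX3, RP11-436F21.1 and SSTR5-AS1, with RUNX1 fold enrichments from 45.5 to 90.7. Such peaks numbered 272 in all, and 59.6% of them were intergenic. Their median RUNX1 fold enrichment was 6.915, so the 10 named are not typical of them. It was 20.63 for RUNX1 peaks in a shared SKI site and 17.08 for those in other SKI peaks. Median fold enrichment on X was 1.31, 1.83, 1.74 and 1.73 times that of the whole list in the 3 SKI lists and the RUNX1 list, so that ranks by fold favour sites on X, such as those at TSR2 and UBL4A.

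SKI peaks that overlapped RUNX1 were the stronger SKI peaks in all 3 lists. The median fold enrichment with and without RUNX1 was 56.9 and 17.5 in unmodified cells, replicate 1, 14.5 and 9.48 in replicate 2, and 17.4 and 10.4 in control cells. The two-sided permutation p was 1e-05 in each list, the smallest that 100000 resamples can give. In the strongest 10% of SKI peaks, 44.5% (43.1 to 45.8), 52.0% (49.5 to 54.6) and 63.6% (61.1 to 66.1) overlapped RUNX1 in the same order of lists, and in the weakest 10% these shares were 0.602%, 9.56% and 9.06%. Of RUNX1 peaks, 77.4% of the strongest 10% and 40.6% of the weakest 10% lay in a shared SKI site. With lists of equal length the difference of medians in replicate 1 was 13.8, against 39.4 with the whole list, and it was 26.1 as a mean over 4 classes of peak width.

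**Figure D1:**
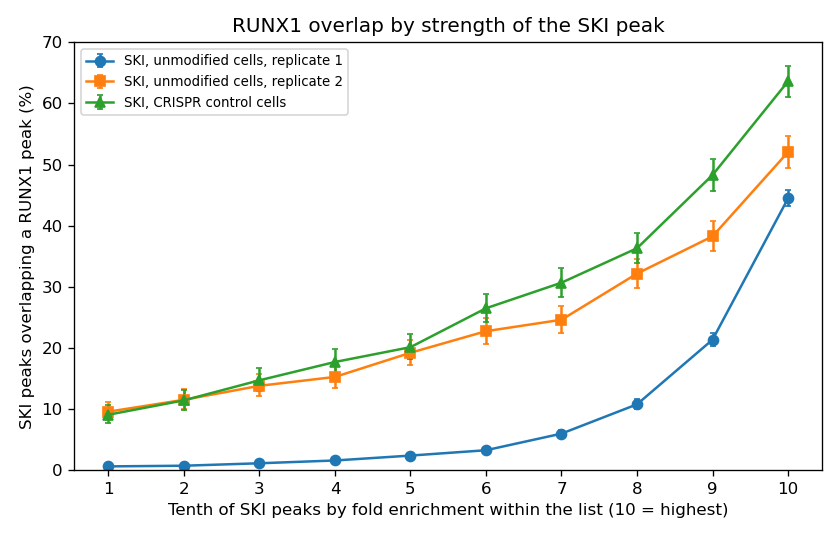
Percentage of SKI peaks overlapping a RUNX1 peak (vertical axis, %) over 10 equal groups of rising fold enrichment within each SKI list (horizontal axis, 10 is the highest), with 95% Wilson intervals. The share is highest in the top group of every list, at 44.5%, 52.0% and 63.6%.

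The third question was where in genes the sites lay. Shared SKI sites were promoter-rich, with 46.2% (95% Wilson interval 45.2 to 47.2) centred within 1000 bp of a TSS, whereas 19.6% (18.5 to 20.6) of RUNX1 peaks were. The odds ratio was 3.53 (Fisher's exact test, two-sided, p = 1.18e-243). The SKI share depended on the list and on the sharing rule. It was 30.3% for regions in any SKI list, and 30.1%, 48.5% and 43.3% for the peaks of the 3 SKI lists. Shared SKI sites split by RUNX1 differed in position, with 24.6% (23.1 to 26.2) at promoters where RUNX1 was present and 57.0% (55.8 to 58.3) where it was not (odds ratio 0.246, Fisher's exact p = 1.59e-192). Read the other way, 17.8% of promoter sites and 46.9% of sites farther from a TSS carried RUNX1. RUNX1 peaks inside shared SKI sites were at promoters in 24.1% of cases and other RUNX1 peaks in 13.7% (odds ratio 2.0, Fisher's exact p = 7.71e-23). In the authors' own position column, intron was the most frequent class of SKI peaks with RUNX1 (34.7%, 34.2% and 34.3%), and the TSS class was the most frequent of those without (36.1%, 60.1% and 56.1%). Regions along a chromosome are not independent, so these exact p-values are too small by an unknown amount.

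**Figure D2:**
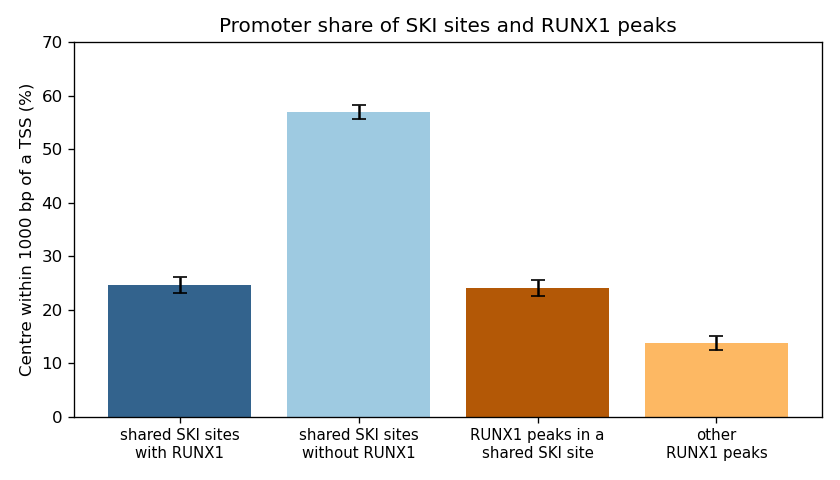
Percentage of regions centred within 1000 bp of a TSS (vertical axis, %) for shared SKI sites with and without RUNX1 and for RUNX1 peaks inside and outside shared SKI sites, with 95% Wilson intervals. SKI sites without RUNX1 stand at 57.0% and the other 3 sets between 13.7% and 24.6%.

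The fourth question was which groups of genes lay near the sites. A shared SKI site was within 10 kb of a TSS of 24 of 30 genes of TGF-beta and SMAD signalling (80.0%, against 25.1% of other protein-coding genes; odds ratio 11.95, Fisher's exact test with Benjamini-Hochberg adjustment over 11 lists, adjusted p = 4.96e-09). Besides SKI and SKIL these included the receptor gene TGFBR1, SMAD2, SMAD3, SMAD4, the inhibitory SMAD7 and the target ID1, at which SKI fold enrichments were 116, 35.4 and 22.7. RUNX1 peaks lay near 9 of the 30 (30%, adjusted exact p = 0.00526).

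Of 36 myeloid maturation genes, 22 had a shared SKI site (odds ratio 4.69, adjusted exact p = 1.92e-05) and 10 a RUNX1 peak (odds ratio 3.43, adjusted exact p = 0.00526). The odds ratio for SKI was 7.65 without WT_SKI replicate 2 and 8.06 with a distance of 50000 bp. It was 4.12 without the control cells, 2.77 among genes with a rebuilt TSS and 2.14 at 1000 bp, where the call was lost. Upstream of MPO, the gene of myeloperoxidase, a site at chromosome 17, 56361265 to 56363296, had SKI fold enrichments of 74.8, 14.2 and 31.0 and a RUNX1 fold enrichment of 28.7. Sites with both proteins also lay at NCF1, a subunit gene of the neutrophil oxidase, at MMP9, where RUNX1 fold enrichment was 74.0, and at TYROBP. Haematopoietic transcription factor genes had the same SKI count, 22 of 36, and a RUNX1 peak at 14 (odds ratio 5.68, adjusted exact p = 4.39e-05). Both proteins were at RUNX1, LMO2, ETV6 and FOS, with RUNX1 fold enrichments of 42.4, 31.6, 10.6 and 15.9, and at CEBPA and MYB.

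Inflammatory signalling genes had a shared SKI site in 17 of 26 cases (odds ratio 5.64, adjusted exact p = 4.82e-05) and a RUNX1 peak in 9 (odds ratio 4.71, adjusted exact p = 0.00254). The site at NFKBIA, the gene of the NF-kappaB inhibitor, had SKI fold enrichments of 81.2, 23.9 and 55.5. CXCL8, IL6R and TNF also had both proteins, the TNF site being nearest to the TSS of LST1. For retinoic acid response genes, 12 of 24 had a shared SKI site (odds ratio 2.98, adjusted exact p = 0.0134) and 11 had a RUNX1 peak (odds ratio 7.55, adjusted exact p = 4.39e-05). RXRA, which encodes a retinoid receptor, had 8 shared SKI sites, 4 with RUNX1, and CD38, PRAM1 and UBA7 also had both proteins. Corepressor complex genes had a shared SKI site in 12 of 24 cases (odds ratio 2.98, adjusted exact p = 0.0134), with both proteins at TBL1X, TBL1XR1 and RCOR1 among others, and a RUNX1 peak in 4 (adjusted exact p = 0.440).

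Ribosomal protein genes had a shared SKI site in 14 of 30 cases (odds ratio 2.61, adjusted exact p = 0.0144), RPL8, RPL19 and RPS18 among them, and a RUNX1 peak in 1 (adjusted exact p = 0.440). Neuronal genes had a shared SKI site in 2 of 28 cases (TUBB3 and GRIN1, odds ratio 0.229, adjusted exact p = 0.0338) and no RUNX1 peak. Only 11 of the 28 had a rebuilt TSS, without which no site could be assigned, and among these 2 of 11 gave an odds ratio of 0.362 (adjusted exact p = 0.332). Liver and muscle genes had 1 of 28 (ACTN2, odds ratio 0.110, adjusted exact p = 0.0134), or 1 of the 6 with a rebuilt TSS (odds ratio 0.326, adjusted exact p = 0.418). B and T lymphoid genes had 5 of 30 (CD3E, CD8A, CD79A, IL7R and CD4, adjusted exact p = 0.399), and erythroid and megakaryocytic genes had 3 of 26 (EPOR, TFRC and NFE2, adjusted exact p = 0.189). Against genes with a TSS rebuilt from the lists, a background chosen after seeing the data, the number of lists with more SKI sites than other genes was 4 and not 7. The calls for corepressor, retinoic acid and ribosomal genes (odds ratios 1.78, 2.45 and 1.63, adjusted exact p = 0.332, 0.137 and 0.332), and the lower calls for neuronal and for liver and muscle genes, were then lost, as were the RUNX1 calls for myeloid maturation (odds ratio 2.22, adjusted exact p = 0.120) and TGF-beta and SMAD signalling (2.63, adjusted exact p = 0.0808). The calls for ribosomal and neuronal genes were also lost without WT_SKI replicate 2 (odds ratios 2.18 and 0.362, adjusted exact p = 0.0641 and 0.0791) and at the stricter threshold (1.54 and 0.275, adjusted exact p = 0.299 and 0.0912). With lists of equal length the neuronal, liver and muscle, and ribosomal calls were lost, and at 1000 bp the myeloid and ribosomal calls were.

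**Figure D3:**
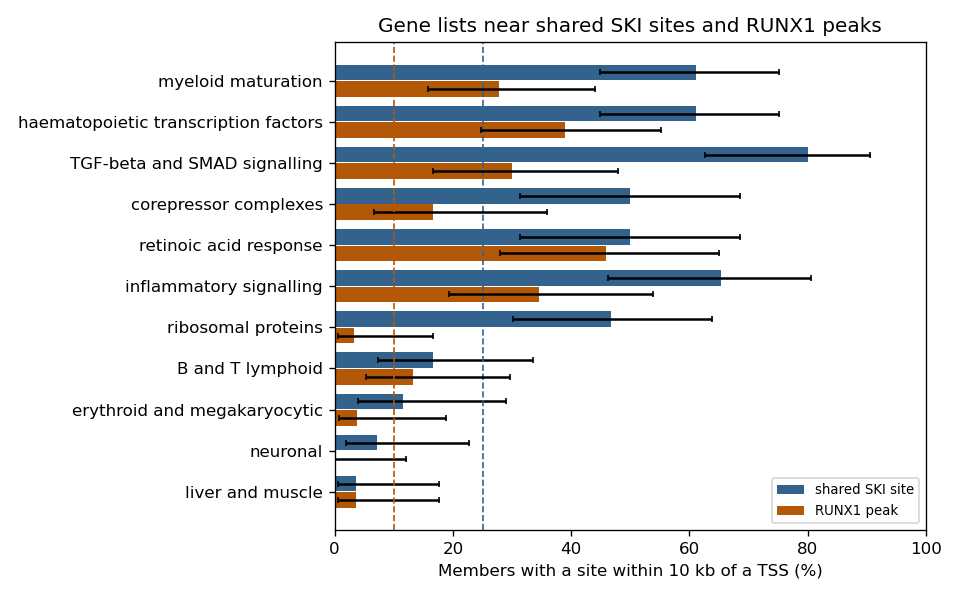
Percentage of the members of 11 gene lists with a shared SKI site or a RUNX1 peak within 10 kb of a TSS (horizontal axis, %), with 95% Wilson intervals. Dashed lines mark the median share among genes outside a list, and TGF-beta and SMAD signalling has the highest SKI share, 80.0%.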

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

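The background of genes with a rebuilt TSS was an alternative chosen after seeing the data, and all others were planned. The overlap of shared SKI sites with RUNX1, the higher fold enrichment of SKI peaks with RUNX1 and the higher promoter share of SKI sites kept their direction and side of the threshold under every alternative run. The fold over expectation ranged from 3.44 for sites near a TSS to 306 for summits within 250 bp, and from 56.2 to 100 when 1 SKI list was left out. The number of shared sites fell to 3121 with lists of equal length, which hold fewer peaks, and was 9581 to 12645 when 1 SKI list was left out. The number of gene lists with more SKI sites than other genes was 4 with the background of genes with a rebuilt TSS, which leaves out genes that were nearest to no peak, and 5 to 7 under the others. Among the odds ratios of single lists, 73 of the 88 alternative values kept both their direction and their side of the threshold, 14 lost their call and 2 turned, 1 value being in both counts. For ribosomal protein genes the odds ratio was 0 with lists of equal length, and for B and T lymphoid genes it was 1.41 with a distance of 50000 bp, neither past the threshold (adjusted exact p = 0.168 and 0.389); the cause was not tested. At 1000 bp the calls for myeloid maturation (odds ratio 2.14, adjusted exact p = 0.0712) and ribosomal protein genes (1.83, adjusted exact p = 0.173) were lost. With lists of equal length those for neuronal genes (0.378, adjusted exact p = 0.623) and for liver and muscle genes (0, adjusted exact p = 0.236) were lost. The motif test and its alternatives were not run. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. Unknown library depth limits what the absence of a peak from a list can show.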

Other observations

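The tests below were chosen after the result was seen, except the comparison of the strongest and weakest peaks of the long SKI list.

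Near 5045 protein-coding genes (25.2%) there was a shared SKI site within 10 kb of a TSS, near 2031 (10.1%) a RUNX1 peak, and near 1370 (6.83%) a shared SKI site that held a RUNX1 peak. Among the 13279 with a rebuilt TSS these shares were 38%, 15.3% and 10.3%. Sites with both proteins lay at 9 of 24 retinoic acid response genes, among them RARA, RXRA, DHRS3, ICAM1 and ASB2 (odds ratio 8.23, Fisher's exact test, adjusted p = 9.76e-05). They lay at 11 of 36 haematopoietic transcription factor genes, among them ERG, FLI1, MYB and CEBPA (odds ratio 6.04, adjusted exact p = 9.76e-05), and at 9 of 36 myeloid maturation genes, among them AZU1, CTSG, LYZ and CAMP (odds ratio 4.57, adjusted exact p = 0.00202). Among genes with a rebuilt TSS alone, the odds ratios were 7.15, 4.58 and 3.02 (adjusted exact p = 0.000828, 0.00124 and 0.0280). TGF-beta and SMAD signalling (7 of 30, odds ratio 4.17, adjusted exact p = 0.00950) and inflammatory signalling (6 of 26, odds ratio 4.11, adjusted exact p = 0.0156) were also called against all genes, but not among genes with a rebuilt TSS (odds ratios 2.91 and 3.08, adjusted exact p = 0.0569 for each). These calls are not independent of the RUNX1 calls above, as every site with both proteins holds a RUNX1 peak. A RUNX1 peak lay near 11 of the retinoic acid, 14 of the haematopoietic and 10 of the myeloid genes. Whether the proteins coincided within a list more often than their separate shares give was not tested. CEBPE, a regulator of granulocyte maturation, had a RUNX1 peak but no shared SKI site.

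The SKI list of unmodified cells, replicate 1, was far longer than the other SKI lists. Its extra peaks may be weak sites under the threshold of the other lists. Of its strongest 10%, 70.4% were found in both others, and of its weakest 10%, 0.164%, a ratio of 429. Strong peaks would recur more often under other explanations too, so this ratio cannot tell weak sites from background peaks. Deeper sequencing of this library stays open. At shared sites the median ratio of its tags was 5.86 over replicate 2 and 5.44 over control cells, but total depth is not known. Fold enrichment at shared sites was higher in this list, with lower quartiles of the ratio of at least 2.50, but the control library behind each list is not known, so values of different lists are not on a common scale and this excludes nothing. No biological explanation was tested.

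RUNX1 peaks lay more often in SKI peaks of control cells (70.7%) than of unmodified cells, replicate 2 (60.4%), with 794 RUNX1 peaks in the former alone and 220 in the latter alone. Wider peaks in control cells did not account for all of it, as the ratio of such peaks was 2.55 (95% exact binomial interval 2.24 to 2.90) by summits within 250 bp. The ratio was 4.15 among distal RUNX1 peaks, which cannot test promoter content, since a list richer in promoters holds fewer distal peaks. Among promoter RUNX1 peaks the ratio was 2.0 (1.43 to 2.82), also towards control cells. Yet replicate 2 had more promoter peaks than the control list (7004 against 6070), so promoter content alone did not account for all of it either. The promoter ratio was by overlap of 1 bp, to which wider control peaks could add, so width and promoter content acting together were not excluded. The design offers the control cells as a biological explanation. But among the 5581 peaks of highest −log10 p in each list RUNX1 was at 44.9% in unmodified cells, replicate 1, at 45.2% in control cells and at 38.6% in replicate 2. The 2 lists of unmodified cells thus differed by more than replicate 1 did from the control cells. Differences in quality between single libraries stay open.

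The background implied by a peak (tags divided by fold enrichment and width), relative to the median chromosome, was 1.31, 1.47, 1.397 and 1.395 on chromosome 18, 1.41, 1.42, 1.28 and 1.27 on 22, and 0.689, 0.617, 0.578 and 0.607 on X, in the order of the 3 SKI lists and RUNX1. A candidate explanation is chromosome copy number, as gains of 18 and 22 and loss of X are known in HL60, and with the trend on peak density removed, chromosome 18 lay 1.88 to 2.45 SD above the line and 8 of the 12 values lay over 1 SD from it in the named direction, while 22 did so in 1 list (1.52, 0.753, 0.877 and 0.682 SD) and chromosome 13, not among the named gains, lay 1.32 to 1.67 SD above in all 4. Chromosomes 17 (-1.08, -0.663, -2.07 and -1.53 SD) and 19 (-1.88, -2.14, -0.861 and -1.48 SD), also not named, lay below the line in all 4 lists. The count of 8 decides nothing, because chromosomes in extra copies would also yield more peaks and the bound of 9 was set after the chromosome values were seen. Density of binding sites had rho of 0.744, 0.685, 0.474 and 0.309 with the background, over the 0.7 it needed in 1 of the 4 lists, and copy number and density cannot be told apart here. Chromosome 17 was lower in control cells (0.769) and RUNX1 (0.880) than in the SKI lists of unmodified cells (1.05 and 1.18), which could come from cells or control libraries of one kind, and across 23 chromosomes such differences correlated with r of 0.457 (permutation p = 0.0268; rho 0.269, permutation p = 0.214) and 0.609 (permutation p = 0.00228; rho 0.364, permutation p = 0.0892) in the 2 pairings, but with r of 0.176 and 0.337 without the 2 farthest chromosomes, so the relation rests on those.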
